A study of Drosophila melanogaster with 35 samples.

How the data were processed

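RNA-seq was measured in 23 head libraries of *Drosophila melanogaster* (WT KDM5, n = 5; A224T, D234G, L854F, R873W, Y874C and JmjC, n = 3 each), and Ribo-Seq in 12 libraries (control and kdm5-knockdown neurons, IP and Input, n = 3 each). Per the labels, heads came from flies kept at 25 °C and harvested 1 to 5 days after eclosion in the morning, with a stranded mRNA kit. The labels do not say whether the replicates of a strain came from separate cultures, so p-values measure the spread between these samples, which may be technical. The sex of the flies is not given in the sources used here.

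The authors' deposited RNA-seq table holds counts per gene, whole numbers for 17830 genes and for transposable element insertions in 23882 features. The submitters' processing notes name fastp, STAR, featureCounts, DESeq2 and the dm6 build. Their versions, the annotation release and the strand option of the counting are not given in the sources used here, so values of overlapping, antisense and paralogous genes are uncertain. For Ribo-Seq only the authors' deposited comparison table was used, with 30704 transcripts. Per the file headers it holds the columns rna, rfp and te, read here as log2 folds of knockdown against control because the submitters' processing notes list DESeq2, whose folds are log2. It also holds adjusted p-values, per the file headers, of these columns, and mean counts averaged by the authors. Per-library Ribo-Seq counts were not analysed here. The Ribo-Seq count tests written before the data were examined, their block, their scalings and the leaving out of single libraries were therefore not run. Instead 1 transcript per gene was kept (13963 genes), calls were taken at the deposited adjusted p under 0.05, and list medians were set beside 10000 random lists matched on mean expression in 20 bins.

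Library totals were 16993600 to 32985400 counts, except D234G 1 (3803080) and D234G 2 (4960380). Transposable element insertions held 0.764 to 1.52% of counts and were left out of the gene tests. Their share was 0.768 ± 0.00613% in D234G (n = 3) against 1.16 ± 0.247% in WT (n = 5, exact permutation p = 0.0357, adjusted p = 0.214), and the other strains had an exact permutation p of 0.107 or more. No 2 replicates agreed within sampling noise (chi-square over degrees of freedom of 7.54 to 149). Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, with DESeq2 1.42.0 as an alternative, and tables and figures in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The main fit used TMM scaling, filterByExpr (12093 genes kept) and the quasi-likelihood F-test of edgeR in 1 means model over the 23 libraries, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p of a head gene comes from this test. Folds are log2, errors of folds are standard errors of that fit, and CPM are TMM-scaled means ± SD. The mean of 5 variants weights each variant equally, and leaves JmjC out.

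The 25 gene lists were written before the data were examined, as were the tests, naming rule and first set of alternatives. Planned head comparisons were each strain and the mean of 5 against WT, their overlaps, JmjC against that mean, and the 5-variant F-test. Comparisons that rest on the 2 sets of libraries, between WT libraries, and of single variants with other variants were added after the data were seen. Each list was tested with camera of limma on voom values (preset correlation 0.01, adjusted over the 25 lists of a comparison), with an estimated correlation and fry beside it. List counts are calls over all genes, followed by calls adjusted over the list alone. The lists, with the symbols found in the data, were cytosolic ribosomal proteins (82), alternative ribosomal protein paralogs (11), mitochondrial ribosomal proteins (75), oxidative phosphorylation (92), mitochondrial genome encoded subunits (13), TCA cycle (16), glycolysis (13), translation factors (52), ribosome biogenesis (32) and proteasome (32). Others were immune effectors (32), heat shock proteins (20), oxidative stress and glutathione (49), P450 (85), stress response (15), synaptic genes (32), neuropeptides (26), photoreceptor (23), glia (16), fat body (15), muscle (20) and hemocyte (11) markers, sex-biased transcripts (9), clock genes (9) and histone methylation enzymes (15). Nol9 and Cry were not found. Genes were named by rule: Kdm5, the 4 largest rises and falls among called genes with a mean of 5 CPM or more and no overlap between the libraries of the 2 groups, and the members of called lists with the smallest p in the direction of the list (3 each for ribosomal, mitochondrial ribosomal and oxidative phosphorylation lists, 2 for others). For the mean of 5 the 10 largest rises and falls among genes called alike in 4 or more variants were taken (195 rose and 179 fell). For Ribo-Seq a mean count of 100 or more in both columns replaced the CPM and overlap rules, a choice made after the table was seen.

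Where 1 group held 0 counts a fold is a lower bound from a floor of 3 counts, and with 1 to 3 counts a count ratio is given with an exact interval, which covers counting error only. For the mean of 5, where a variant held only 0 counts, this rule was set after the value was seen: 296 tested genes had 0 counts in 1 or more variants, 36 of them were called in that mean, and 1, mthl8, is named. The 2 sets of libraries were defined from the data, by 5 CPM of roX2. The control subsets, the leaving out of D234G and R873W libraries with male reproductive transcripts, the inclusion of transposable element insertions and the mean count minimum for Ribo-Seq were alternatives added after the data were seen. Alternatives written before the data were examined were RLE scaling, library size only, DESeq2, no filter, a filter of 5 CPM in 3 libraries, only WT and 1 strain in the fit, the replicate number as a block, a fold of 1.5 or more, and leaving out each library. Replicate numbers did not pair libraries (63 pairs, median correlation of residuals -0.0139), so the block stays an alternative. The pipeline was tested on simulated data with 200 changed genes per strain: 57 to 73% were recovered at 1.5-fold and 74 to 89% at 2-fold, false calls were 1.96 to 7.06%, and a list shift of -0.3 was found as -0.28 to -0.30 with 0 of 24 other lists called. Library composition was also compared by a table of 26 male reproductive markers.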

Results

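KDM5 is a chromatin enzyme that removes methyl groups from lysine 4 of histone H3, and the head libraries came from flies carrying WT KDM5, 1 of 5 missense changes, or the demethylase-dead change JmjC. The 23 libraries fell into 2 sets by roX2, an RNA of the male dosage compensation complex. Each strain lay within 1 set, and only WT crossed both. Set 1 held WT 1 and 2 with all D234G, R873W and Y874C libraries, at 19.5 to 40.4 CPM of roX2. Set 2 held WT 3 to 5 with all A224T, L854F and JmjC libraries, at 0.142 to 0.941 CPM. roX1, the partner of roX2, spanned 526 to 859 CPM in set 1. Within set 2 it spanned 12.6 to 13.9 CPM in WT, 181 to 219 CPM in A224T, 86.0 to 95.2 CPM in L854F and 278 to 337 CPM in JmjC. Yp1, a yolk protein made by female fat body, spanned 1747 to 4445 CPM in set 1 and 7528 to 13970 CPM in set 2. The antennal genes Orco, the odorant co-receptor, and Obp83b, an odorant-binding protein, spanned 4.70 to 9.61 CPM and 1.45 to 7.95 CPM in set 1, against 41.5 to 75.0 CPM and 51.2 to 121 CPM in set 2. Between WT 3 to 5 and WT 1 and 2, of 1 genotype, 1738 genes were higher and 1595 lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Oxidative phosphorylation genes, whose proteins make ATP in mitochondria, were lower in WT 3 to 5, with a median log2 fold of -0.44 (camera adjusted p = 1.95e-16, 0.344 with an estimated correlation). Values against the WT libraries of a strain's own set are called same-set values. For JmjC against the mean of 5 variants, same-set instead means JmjC against the mean of A224T and L854F, with no WT library.

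**Figure D1:**
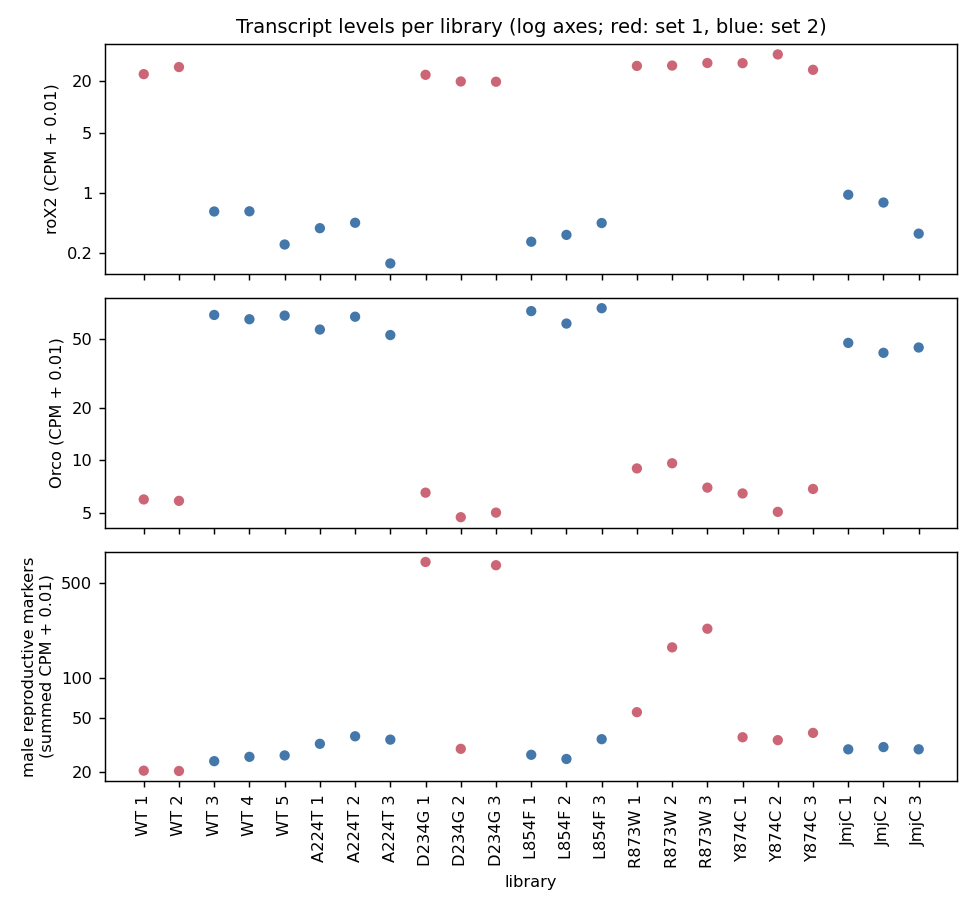
CPM of marker transcripts (y, log scale) in each of the 23 head libraries (x, grouped by genotype), with 1 point per library. roX2 was 19.5 to 40.4 CPM in set 1, and at most 0.941 CPM in set 2.

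Transcripts of Kdm5 itself (2L 5989400 to 5999501) were detected in every library of each strain. Kdm5 measured 482 ± 33.9 CPM in WT (n = 5), 572 ± 5.54 CPM in R873W (n = 3) and 549.5 ± 25.8 CPM in D234G (n = 3). It rose in R873W by a log2 fold of 0.25 ± 0.058 (edgeR adjusted p = 0.00223, same-set 0.29, adjusted p = 0.00342) and in D234G by 0.19 ± 0.058 (edgeR adjusted p = 0.0125, same-set 0.23, adjusted p = 0.0162). The D234G value was 0.14 without WT 2 (edgeR adjusted p = 0.0715) and 0.09 without D234G 2 (0.323). It was 0.12 with no filter (0.153) and 0.21 with only WT and D234G in the fit (0.0768). Log2 folds were 0.11 in A224T (edgeR adjusted p = 0.232), 0.16 in L854F (0.107) and 0.12 in Y874C (0.164), each ± 0.058. In L854F Kdm5 passed without WT 5 (0.20, edgeR adjusted p = 0.0318), in the replicate block (0.22, 0.0273) and by DESeq2 (0.16). JmjC held 454 ± 18.3 CPM, a log2 fold of -0.087 ± 0.058 against WT (edgeR adjusted p = 0.297).

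Cytosolic ribosomal proteins build the 40S and 60S subunits that translate all nuclear-encoded messages, and the study named this gene family from these same samples, so the values below are not independent evidence for it. The list of 82 genes fell in A224T, D234G, L854F, R873W and JmjC, while most of its members did not pass in Y874C. In A224T the median log2 fold was -0.41 (camera adjusted p = 5.66e-29, 0.244 with an estimated correlation). In this list 0 rose and 60 fell (0 and 71 in the list alone). RpL4, of the 60S subunit, measured 949.8 ± 58.3 CPM (n = 3) against 1456 ± 86.7 CPM in WT (n = 5), and RpS16, of the 40S subunit, and RpL14 fell by log2 folds of 0.70 and 0.63. In L854F the median was -0.37 (camera adjusted p = 4.54e-33, 0.169 with an estimated correlation). Of the members tested, 0 rose and 43 fell (0 and 66 in the list alone). RpL4 (-0.52), RpL27 (-0.61) and RpL14 (-0.62) led this decrease. In D234G the median was -0.42 (camera adjusted p = 9.68e-21, 0.272 with an estimated correlation). By single genes, 0 rose and 56 fell (0 and 57 in the list alone). RpS4 measured 713 ± 41.3 CPM against 1204 ± 96.3 CPM in WT, with RpL4 at -0.66 and RpS13 at -0.60. In R873W the median was -0.24 (camera adjusted p = 1e-07, 0.599 with an estimated correlation), and 4 of 56 random splits of its and the WT libraries gave one as large. Here 0 rose and 41 fell (0 and 41 in the list alone). RpL36A fell to 89.2 ± 10.6 CPM from 469.7 ± 95.4 CPM, and RpL27 (-0.84) and RpL21 (-0.89) fell less far.

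Y874C differed within the same family of ribosomal protein genes. Its median was -0.052 (camera adjusted p = 0.379). Among these genes, 6 rose and 10 fell (6 and 10 in the list alone). RpL39 and RpL41, which encode very small 60S proteins, fell with RpL21. RpL39 measured 55.8 ± 15.6 CPM against 325 ± 165 CPM in WT, RpL41 456 ± 144 against 1028 ± 125 CPM, and RpL21 had a log2 fold of -0.64 ± 0.098. The median was 0.02 without WT 3 and 0.01 without Y874C 1. With the replicate number as a block the list was lower, at -0.066 (camera adjusted p = 0.0286), and 1 rose and 13 fell. The control of that fit was WT 1 to 3 only. The difference was tested directly, in a comparison chosen after the results were seen. Y874C against the mean of D234G and R873W, all of set 1, had a ribosomal protein median of 0.34 (camera adjusted p = 1.18e-19, 0.673 with an estimated correlation). Among these genes, 60 rose and 1 fell (64 and 3 in the list alone). Against the mean of the 4 other variants it was 0.35 (camera adjusted p = 1.09e-19, 0.883 with an estimated correlation). JmjC fell with the 4 variants, with a median of -0.42 (camera adjusted p = 1.52e-24, 0.227 with an estimated correlation). In this list 0 rose and 70 fell (0 and 75 in the list alone). RpL4 (-0.55), RpL14 (-0.61) and sta, a 40S protein (-0.58), had the smallest p among those that fell. Same-set medians were -0.39 in A224T, -0.36 in L854F, -0.40 in D234G, -0.22 in R873W, -0.44 in JmjC and 0.0065 in Y874C. Of all camera calls in this report, none against all WT libraries held with an estimated correlation, and 3 same-set calls did. These were ribosome biogenesis in L854F (adjusted p = 0.0149), and neuropeptides in JmjC against WT (adjusted p = 0.0308) and against A224T and L854F (adjusted p = 0.0092).

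**Figure D2:**
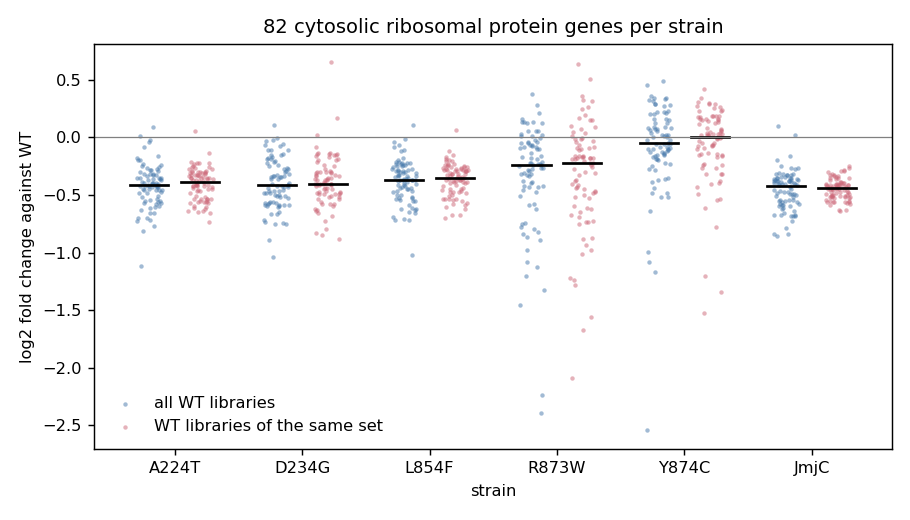
Log2 fold against WT (y) of each of the 82 cytosolic ribosomal protein genes (points) in each strain (x), with the list median as a line. Medians were -0.41 in A224T and -0.052 in Y874C.

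A224T and L854F, both of set 2, both had lower translation machinery and clock repressors and higher glutathione enzymes. In A224T 870 genes rose and 916 fell against all WT libraries, and 1023 and 1112 same-set. With library size as the only scaling the A224T counts were 1319 and 520, and leaving out A224T 1 or A224T 3 left 948 or 930 calls in all. In L854F 530 rose and 412 fell (681 and 690 same-set), and without L854F 1, 2 or 3 there were 444, 395 or 591 calls. Tested against each other, A224T and L854F differed at 788 genes. mthl8, which encodes a methuselah-like receptor, had 1 count over the 5 WT libraries and reached 52.7 ± 9.06 CPM in A224T and 50.2 ± 11.5 CPM in L854F. Its count ratios were 4742 [851, 187374] and 4547 [815, 179649], with intervals that cover counting error only. lncRNA:CR44946, a noncoding RNA, rose from 2.57 ± 0.604 CPM to 20.4 ± 2.91 CPM in A224T (edgeR adjusted p = 1.37e-10), with a log2 fold of 2.55 ± 0.15 in L854F (edgeR adjusted p = 1.85e-09). CG5653 rose in A224T from 1.41 ± 0.347 to 12.3 ± 1.93 CPM (edgeR adjusted p = 3.72e-08), and Edg91, a cuticle gene, by 2.63 ± 0.39. In L854F the noncoding RNA CR43972 rose by 3.92 ± 0.21 and Acsx4, an acyl-CoA synthetase, by 3.40 ± 0.35. hoka, needed for smooth septate junctions of the gut, fell in L854F by a log2 fold of 5.87 (edgeR adjusted p = 1.01e-05). mt:ND2, a complex I subunit made in mitochondria, had log2 folds of -3.50 ± 0.69 in A224T (same-set -1.57) and -3.10 ± 0.68 in L854F (same-set -1.17).

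Several of the largest decreases in these strains did not pass without single libraries. Srg3 had a log2 fold of -4.17 ± 0.72 in A224T (edgeR adjusted p = 0.000625), and -2.02 ± 0.60 in L854F (edgeR adjusted p = 0.0429), where it was -2.27 to -1.84 but did not pass without WT 1 (edgeR adjusted p = 0.0676), WT 2 (0.0674), WT 3 (0.0670) or any 1 L854F library (0.0981, 0.158 and 0.161). Lsp1beta, a storage protein, was -3.58 ± 0.86 in A224T (edgeR adjusted p = 0.00823, same-set -1.66, adjusted p = 0.054), with an edgeR adjusted p of 0.0560 without A224T 3. CG13947 in A224T had 1 count and a ratio of 0.00161 [4.07e-05, 0.00898] (edgeR adjusted p = 0.0381), which did not pass without WT 3 (log2 fold -7.30, edgeR adjusted p = 0.0702) or without A224T 1, 2 or 3 (0.140, 0.120 and 0.139). CG16826 in L854F measured 0.503 ± 0.242 CPM against 451 ± 678 CPM in WT (edgeR adjusted p = 0.0324), and did not pass without L854F 1, 2 or 3 (-9.54, -9.67 and -10.25; 0.134, 0.141 and 0.114).

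Ribosome assembly genes fell as well in A224T and L854F, against all WT and same-set. Ribosome biogenesis factors, which make rRNA and assemble subunits, had a median of -0.32 in A224T (camera adjusted p = 2.44e-06, 0.441 with an estimated correlation). In this list 0 rose and 11 fell (0 and 14 in the list alone). Fib, the rRNA methyltransferase, fell by 0.74 and Ns3, a GTPase, by 0.31. In L854F the median was -0.38 (camera adjusted p = 6.92e-09, 0.407 with an estimated correlation). Of the members tested, 0 rose and 5 fell (0 and 19 in the list alone). Translation factors had medians of -0.12 in A224T (camera adjusted p = 0.00347, 0.652 with an estimated correlation) and -0.12 in L854F (camera adjusted p = 2.93e-05, 0.407 with an estimated correlation). In L854F eIF3a, the scaffold of the 43S complex, fell by 0.55, and the helicase eIF4A fell by 0.40 in A224T and by 0.35 in L854F. Same-set medians in A224T and L854F were -0.50 and -0.51 for ribosome biogenesis, and -0.14 and -0.20 for translation factors. With WT 1 and 2 only they were 0.031 and -0.010, and 0.028 and -0.015, none called (camera adjusted p of 0.364 or more). In L854F Ns3 (-0.27) did not pass without L854F 2 (edgeR adjusted p = 0.0915), and Ns2 (-0.39) not without L854F 1 (0.0522) or L854F 2 (0.0833). Oxidative stress and glutathione enzymes had medians of 0.29 in A224T (camera adjusted p = 6.69e-06, 0.428 with an estimated correlation) and 0.17 in L854F (camera adjusted p = 0.001, 0.45 with an estimated correlation, 0.08 without L854F 1). GstD3, a glutathione transferase, rose by 0.69 ± 0.094 in A224T and 0.56 ± 0.095 in L854F, GstE3 rose by 0.77 ± 0.10 in L854F, and the peroxiredoxin Prx6c rose by 2.49 ± 0.39 in A224T (1.45 without A224T 2). Clock genes had medians of -0.16 in A224T (camera adjusted p = 0.0297, 0.244 with an estimated correlation) and -0.19 in L854F (camera adjusted p = 0.00364, 0.0887 with an estimated correlation, -0.09 without WT 2). per, the period repressor, measured 23.9 ± 1.99 CPM in A224T against 58.6 ± 19.5 CPM in WT and fell by 1.25 in L854F, and vri, a bZIP repressor, fell by 0.98 and 1.34. WT itself was uneven for per, at 24.7 CPM in WT 5 and 61.2 CPM in the next lowest WT library. The A224T clock list did not pass without WT 3 (camera adjusted p = 0.0617) or A224T 3 (0.0646).

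Neuronal genes fell in A224T, and the gap to L854F was tested. Synaptic genes had a median of -0.21 in A224T (camera adjusted p = 5.41e-08, 0.528 with an estimated correlation). By single genes, 0 rose and 11 fell (0 and 15 in the list alone). Gad1, which makes GABA, measured 386 ± 18.7 CPM against 576 ± 46.4 CPM, and VGlut, the vesicular glutamate transporter, fell by 0.64. Neuropeptides had a median of -0.37 (camera adjusted p = 0.00044, 0.428 with an estimated correlation, -0.18 without WT 1), with AstC at -0.67 ± 0.072 and Tk, tachykinin, at -0.89 ± 0.11. The list medians in L854F were -0.081 for synaptic genes (camera adjusted p = 0.0665) and 0.093 for neuropeptides (camera adjusted p = 0.307), and the A224T to L854F medians tested directly were -0.15 (camera adjusted p = 2.85e-06, 0.942 with an estimated correlation) and -0.36 (camera adjusted p = 7.95e-10, 0.0636 with an estimated correlation). Photoreceptor genes had medians of -0.21 in A224T (camera adjusted p = 3.82e-05, 0.428 with an estimated correlation) and -0.14 in L854F (camera adjusted p = 0.000463, 0.45 with an estimated correlation), with norpA, the phospholipase C of phototransduction, at -0.45 and -0.42, inaC lower in A224T (-0.24), and the blue opsin Rh5 at 114 ± 6.02 CPM in L854F against 219 ± 43.2 CPM.

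Mitochondrial lists of A224T and L854F depended on the control libraries. Mitochondrial ribosomal proteins had medians of -0.12 (camera adjusted p = 0.0251, 0.841 with an estimated correlation) and -0.14 (camera adjusted p = 0.00332, 0.769 with an estimated correlation), against same-set values of 0.045 and 0.05. mRpL39 fell by 0.38 in A224T and 0.72 in L854F, with mRpL10 (-0.50), mRpL45 (-0.23 and -0.29) and mRpS35 (-0.52). Oxidative phosphorylation medians were -0.11 (camera adjusted p = 0.0297, 0.841 with an estimated correlation) and -0.099 (camera adjusted p = 0.0493, 0.778 with an estimated correlation). Same-set they were above 0, at 0.11 (camera adjusted p = 0.058) and 0.11 (camera adjusted p = 0.0125), so the L854F list was called in the opposite direction. Of its leading members ATPsynE (-0.33, same-set -0.16) and SdhA (-0.25, same-set -0.13) passed in A224T, and ND-75 (-0.29), ND-23 (-0.34), ND-30 (-0.37) and COX8 (-0.55) did not. ATPsynE did not pass without WT 1, WT 2 or any 1 A224T library (edgeR adjusted p = 0.0866, 0.0711, 0.164, 0.0584 and 0.104), nor SdhA without WT 1, WT 2, A224T 1 or A224T 3 (0.0857, 0.0677, 0.172 and 0.197). ND-75 passed without WT 3, WT 4, WT 5 or A224T 2 (edgeR adjusted p = 0.0326, 0.0241, 0.0251 and 0.047), and ND-23, ND-30 and COX8 passed without WT 4 (0.0426, 0.0416 and 0.0499) or WT 5 (0.0351, 0.0433 and 0.0246). mRpL10 in A224T did not pass without A224T 1, 2 or 3 (edgeR adjusted p = 0.0824, 0.0537 and 0.0618), nor mRpL45 without A224T 1 or 3 (0.0816 and 0.0796). Proteasome genes in L854F had a median of -0.12 (camera adjusted p = 0.017, 0.769 with an estimated correlation) and 0.0054 same-set, with Rpn12 at -0.27 and Prosalpha3 at -0.28, neither of which passed. Mitochondrial ribosomal proteins were lost in A224T without WT 1, WT 2 or A224T 2 (camera adjusted p = 0.272, 0.379 and 0.0785) and in L854F without WT 1 or WT 2 (0.0968 and 0.131). Oxidative phosphorylation was lost in A224T without WT 1, 2 or 3 or A224T 1 or 3 (camera adjusted p = 0.491, 0.396, 0.0617, 0.224 and 0.118) and in L854F without WT 1, 2 or 3 or L854F 2 or 3 (0.601, 0.434, 0.0629, 0.0739 and 0.186). Proteasome genes in L854F were lost without WT 1, WT 2 or L854F 3 (camera adjusted p = 0.273, 0.131 and 0.0764).

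D234G heads had higher proteasome, respiratory chain and muscle genes and lower translation, hemocyte and P450 genes. 3058 genes rose and 2292 fell, and 2457 and 1295 same-set. D234G 1 and 2 held 3803080 and 4960380 counts, fewer than any other library. With D234G 2 alone (n = 1, the spread coming from other groups) 593 rose and 569 fell, and with only WT and D234G in the fit 1405 and 945. D234G 1 and 3 carried male reproductive transcripts (711 and 673 CPM summed over 26 markers, against 29.8 CPM in D234G 2 and 20.5 to 26.7 CPM in WT). Among the largest rises Spn77Bb, a serpin, reached 85.8 ± 136 CPM with a log2 fold of 10.16 ± 2.01 (edgeR adjusted p = 0.000585). The count ratios of 3 further genes were 2869 [981, 13919] for CG14893, 1369 [378, 11320.2] for CG3517 and 1141 [389, 5541] for CG15219. In D234G 2 alone (n = 1) the log2 folds were 1.52 for Spn77Bb, 2.89 for CG3517 and 4.69 for CG15219. Among decreases, Drsl4, a drosomycin-like peptide, had a log2 fold of -4.92 ± 1.14 (edgeR adjusted p = 0.00175, same-set -6.10) and CG4757 of -3.36 ± 0.59 (edgeR adjusted p = 0.000154, same-set -4.08). The antennal Obp83b (-3.79) and the esterase Jhedup (-3.59) had same-set values of -0.45 (edgeR adjusted p = 0.25) and -0.62 (edgeR adjusted p = 0.115), so these decreases did not hold within set 1.

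Protein degradation and energy genes rose together in D234G. Proteasome genes, which encode the 20S core and 19S cap, had a median of 0.78 (camera adjusted p = 3.3e-16, 0.3 with an estimated correlation), 0.57 same-set. Here 32 rose and 0 fell (32 and 0 in the list alone). Rpn10, the ubiquitin receptor of the cap, measured 120.4 ± 4.31 CPM against 72.4 ± 6.87 CPM, and the ATPase Rpt5 rose by 0.76 ± 0.095. Oxidative phosphorylation had a median of 0.63 (camera adjusted p = 3.45e-19, 0.3 with an estimated correlation), 0.35 same-set. Among these genes, 75 rose and 0 fell (77 and 0 in the list alone). COX7AL2, a cytochrome oxidase paralog, rose from 15.4 ± 3.03 to 51.0 ± 7.09 CPM, and ATPsyndelta and ATPsynC of the ATP synthase rose by 0.92 ± 0.10 and 0.63 ± 0.078. The TCA cycle (0.31, camera adjusted p = 0.000383, 0.308 with an estimated correlation) rose with Idh3a (0.57) and the citrate synthase kdn (0.58). Glycolysis (0.33, camera adjusted p = 0.00214, 0.308 with an estimated correlation) rose with Pglym78 (0.51) and Pgk (0.48). Without D234G 2 neither list passed (adjusted p = 0.124 and 0.176 by camera). Muscle genes had a median of 0.99 (camera adjusted p = 1.23e-10, 0.272 with an estimated correlation), 0.75 same-set, with the troponin TpnC25D at 1.1 ± 0.099 and Mlp84B at 0.89 ± 0.094. Synaptic genes were at 0.15 (camera adjusted p = 0.00491, 0.698 with an estimated correlation), 0.05 without D234G 2 (camera adjusted p = 0.795) and 0.065 same-set (camera adjusted p = 0.206), yet ple, the tyrosine hydroxylase of dopamine synthesis, rose to 345 ± 103 CPM from 143 ± 18.1 CPM and Gad1 by 0.52 ± 0.069. Mitochondrial ribosomal proteins had a median of 0.13 (camera adjusted p = 0.121).

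Translation and hemocyte genes fell in D234G. Ribosome biogenesis had a median of -0.49 (camera adjusted p = 1.22e-05, 0.308 with an estimated correlation), -0.20 same-set, led by the nucleolar proteins Nopp140 (-0.89 ± 0.12) and Nnp-1 (-0.75 ± 0.13). Translation factors had a median of -0.25 and a mean of 0.47, opposite in sign (camera adjusted p = 6.34e-05, 0.308 with an estimated correlation). The positive mean came from D234G 1 and 3, at 6.10 and 6.26 log2 CPM, against 5.30 in D234G 2 and 5.50 to 5.89 in WT. In this list 8 rose and 26 fell (8 and 26 in the list alone). eEF1alpha1, the main elongation factor, fell by 1.36 (same-set -0.80) and eEF1beta by 0.66. Integrated and unfolded protein stress genes (-0.27, camera adjusted p = 0.00263, 0.272 with an estimated correlation) fell with crc, the fly ATF4 (-0.88 ± 0.094), and Ire1 (-0.41). P450 enzymes (-0.40, camera adjusted p = 0.00119, 0.308 with an estimated correlation) fell with Cyp6t3 (-2.80 ± 0.19) and Cyp12a5 (-1.57 ± 0.13). Immune effectors (-0.79, camera adjusted p = 0.0319, 0.703 with an estimated correlation) were -0.35 without WT 4, and did not pass without WT 1, WT 2, D234G 1 or D234G 2 (camera adjusted p = 0.0858, 0.158, 0.0569 and 0.0609), nor with WT 3 to 5 only (0.298). The thioester proteins Tep2 (-0.95) and Tep4 (-0.63) fell. Hemocyte genes (-0.72, camera adjusted p = 0.00212, 0.361 with an estimated correlation, same-set -0.23) fell with the GATA factor srp (-0.90) and the scavenger receptor Sr-CI (-1.33). Fat body genes had a median of -0.69 and a mean of 0.10 (camera adjusted p = 0.0162, 0.361 with an estimated correlation), -0.41 without D234G 2 (camera adjusted p = 0.054), and -0.16 same-set (camera adjusted p = 0.206), with AkhR (-1.81, same-set -0.78) and apolpp (-1.30, same-set -0.58). Clock genes (-0.44, camera adjusted p = 0.00336, 0.118 with an estimated correlation) fell with cyc (-0.56) and vri (-1.40), and histone methylation enzymes (-0.094, camera adjusted p = 0.0134, 0.383 with an estimated correlation) with the demethylase Kdm2 (-0.46) and the H3K27 methyltransferase E(z) (-0.54). This last list did not pass in the replicate block (camera adjusted p = 0.0738), with the stricter filter (0.061) or with WT 3 to 5 only (0.0624).

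R873W heads combined higher muscle, synaptic and mitochondrial-genome transcripts with lower ribosome biogenesis and mitochondrial ribosomal protein genes. 2645 genes rose and 2639 fell, and 2290 and 2270 same-set (2026 in all with R873W 1 alone, n = 1). CG8851 had 1 count in WT and reached 62.1 ± 3.35 CPM, a ratio of 5591 [1003, 220895]. The other 3 largest rises stood highest in R873W 3, which also held the most male reproductive RNA of this strain. Anp, an antibacterial peptide of the ejaculatory duct, had 0 counts in WT and was at least 480.0-fold higher (edgeR adjusted p = 0.00787), but did not pass without R873W 3 (edgeR adjusted p = 0.0821). CG17097 and CG31872 had ratios of 2554 [707, 21099] and 1558 [431, 12873], and log2 folds of 5.78 and 5.65 in R873W 1 alone (n = 1). Adh, the alcohol dehydrogenase, fell from 14.7 ± 6.65 to 0.205 ± 0.0934 CPM (edgeR adjusted p = 1.76e-07), and the noncoding lncRNA:CR34335, Drsl4 and CG15093 had log2 folds of -5.51 ± 0.57, -4.49 ± 0.98 and -4.29 ± 0.81 (same-set -1.32). Muscle genes had a median of 0.81 (camera adjusted p = 2.46e-09, 0.572 with an estimated correlation), 0.62 same-set, with TpnC25D (1.20 ± 0.098) and the thick-filament protein Mf (0.95 ± 0.086) in front. Synaptic genes had a median of 0.28 (camera adjusted p = 2.25e-07, 0.599 with an estimated correlation), 0.21 same-set, and ple reached 349 ± 57.0 CPM against 143 ± 18.1 CPM, with the scaffold dlg1 at 0.43 ± 0.057.

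In R873W transcripts of the mitochondrial genome rose while genes of the mitochondrial ribosome fell. Mitochondrial genome encoded subunits rose by a median of 0.71 (camera adjusted p = 0.000485, 0.585 with an estimated correlation), 0.85 same-set, and mt:CoII measured 5574 ± 792 CPM against 2353 ± 353 CPM, with mt:ND5 at 1.85 ± 0.26. Nuclear mitochondrial ribosomal proteins, which translate those messages, fell by a median of 0.22 (camera adjusted p = 0.000437, 0.697 with an estimated correlation), -0.37 same-set. Of the members tested, 2 rose and 28 fell (2 and 28 in the list alone). mRpS31 (-0.67 ± 0.10), mRpS26 (-0.98 ± 0.16) and mRpS18A (-1.08 ± 0.18) had the smallest p among those that fell. Nuclear oxidative phosphorylation had a median of 0.24 against all WT (camera adjusted p = 0.0109, 0.731 with an estimated correlation), 0.16 and 0.14 without WT 4 or WT 5 (camera adjusted p = 0.0577 and 0.0845), and -0.075 same-set (camera adjusted p = 0.38), so it did not hold within set 1, although ATPsynC (0.67 ± 0.077), ND-ACP (0.75 ± 0.11) and COX7A (0.70 ± 0.11) rose. TCA cycle (0.18, camera adjusted p = 0.0265, 0.611 with an estimated correlation) and glycolysis (0.23, camera adjusted p = 0.00841, 0.599 with an estimated correlation) genes rose, with Idh3a (0.56), Ogdh (0.35), Pfk (0.36) and Gapdh2 (0.35). The TCA list did not pass without R873W 3 (camera adjusted p = 0.105). In R873W 1 alone (n = 1) the values were 0.13 for TCA, 0.15 for glycolysis and 0.21 for Pfk. Ribosome biogenesis genes fell by a median of 0.68 (camera adjusted p = 7.19e-10, 0.572 with an estimated correlation), -0.41 same-set, with Gar1 of the pseudouridylation complex (-1.11 ± 0.14) and peng (-0.67 ± 0.09). Translation factors had a median of -0.31 and a mean of 0.083 (camera adjusted p = 4.51e-05, 0.585 with an estimated correlation), with eIF5B (-0.74 ± 0.081) and the anti-association factor eIF6 (-1.02 ± 0.12).

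Y874C heads had higher muscle and metabolic genes. 1121 genes rose and 1213 fell (828 and 717 same-set), and 1362 or 1238 passed without Y874C 2 or Y874C 3. Directly compared, D234G and Y874C differed at 4363 genes, R873W and Y874C at 3444, and D234G and R873W at 5310. mthl8 reached 84.9 ± 7.27 CPM, a ratio of 7614 [1366, 300769], and IntS12, a subunit of the Integrator complex, rose from 2.27 ± 0.488 to 14.9 ± 2.96 CPM (edgeR adjusted p = 3.28e-08). The cuticle gene Vajk3 (2.68 ± 0.59, 3.37 without WT 1) and CG4408 (2.46 ± 0.37) rose too. hoka had a count ratio of 0.00286 [0.000346, 0.0104]. The antennal genes Obp19a (-5.45 ± 0.97), a5 (-5.35 ± 0.97) and Os-C (-4.90 ± 0.89) had same-set values of -1.40, -1.21 and -1.18, the antennal genes being low in set 1. Muscle genes had a median of 0.58 (camera adjusted p = 1.63e-09, 0.421 with an estimated correlation), 0.34 same-set, with TpnC25D (1.00 ± 0.098) and paramyosin Prm (1.27 ± 0.19). The TCA cycle (0.31, camera adjusted p = 6.04e-07, 0.421 with an estimated correlation, same-set 0.33) rose with Idh3a (0.55) and Idh3b (0.48), and glycolysis (0.25, camera adjusted p = 0.000504, 0.421 with an estimated correlation, same-set 0.26) with Pgk (0.47) and Pglym78 (0.45).

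Other Y874C families depended on the control libraries. Oxidative phosphorylation had a median of 0.39 (camera adjusted p = 1.76e-09, 0.597 with an estimated correlation) but 0.12 same-set (camera adjusted p = 0.0871), with the ATP synthase subunit blw (0.64 ± 0.082), ND-ACP (0.73 ± 0.11) and ATPsynC (0.51 ± 0.078) in front. Ribosome biogenesis (-0.47, camera adjusted p = 4.23e-08, 0.421 with an estimated correlation) was -0.14 same-set (camera adjusted p = 0.0163), with the nucleolar mbm (-0.94 ± 0.16) and Nopp140 (-0.56 ± 0.11, same-set adjusted p = 0.0558 by edgeR). Translation factors (-0.21, camera adjusted p = 0.000794, 0.597 with an estimated correlation) were -0.039 same-set (camera adjusted p = 0.261), and neither eIF3j (-0.46) nor eIF5B (-0.35) passed same-set (adjusted p = 0.141 and 0.0603 by edgeR). eIF5B was -0.25 without Y874C 1 (edgeR adjusted p = 0.0505). P450 genes (-0.20, camera adjusted p = 0.0321, 0.597 with an estimated correlation) were -0.084 same-set (camera adjusted p = 0.105) and did not pass without WT 3 or Y874C 3 (camera adjusted p = 0.114 and 0.145), with Cyp6t3 (-1.18 ± 0.15) and Cyp6d2 (-2.13 ± 0.33) lower. Neuropeptides (0.24, camera adjusted p = 0.0321, 0.597 with an estimated correlation) were 0.078 same-set (camera adjusted p = 0.835) and did not pass without WT 3, 4 or 5 or Y874C 1 (camera adjusted p = 0.0527, 0.0576, 0.124 and 0.131). Nplp3 (0.91) and Proc (0.37, edgeR adjusted p = 0.0621 without Y874C 1) led this list. Mitochondrial ribosomal proteins had a median of 0.044 (camera adjusted p = 0.32) and -0.13 same-set (camera adjusted p = 0.00129), opposite in sign.

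JmjC heads, which carry KDM5 without demethylase activity, had higher immune genes and lower neuropeptide, synaptic and mitochondrial genes. 1458 genes rose and 1785 fell (1380 and 1720 same-set), and 2084 passed without JmjC 2. With library size as the only scaling the counts were 2652 and 933 and the median of all genes stood 0.14 higher on the log2 scale, so each JmjC change is relative to that shift. Immune effectors had a median of 1.65 (camera adjusted p = 4.71e-06, 0.331 with an estimated correlation), 1.06 without JmjC 2 and 2.03 same-set. By single genes, 21 rose and 0 fell (22 and 0 in the list alone). The diptericins DptA and DptB, antibacterial peptides of the Imd pathway, reached 482 ± 434 and 389 ± 299 CPM, with log2 folds of 6.03 ± 1.27 and 5.30 ± 1.1 (6.98 and 6.11 without WT 4). The infection-induced edin reached 52.8 ± 65.9 CPM (log2 fold 8.69 ± 1.12, edgeR adjusted p = 2.77e-05, 6.96 without JmjC 2), and Tep2 rose by 0.93 ± 0.12. Hemocyte genes (0.36, camera adjusted p = 0.00511, 0.375 with an estimated correlation) were 0.32 same-set (camera adjusted p = 0.0688), with the phagocytic receptor eater (1.29 ± 0.23) and hemolectin Hml (0.75 ± 0.16). Fat body genes (0.59, camera adjusted p = 0.00937, 0.331 with an estimated correlation) were 0.38 without WT 1 and 0.23 same-set (camera adjusted p = 0.464), with the amylase Amy-p (2.07 ± 0.34) and Fatp1 (0.59 ± 0.11). P450 genes (0.29, camera adjusted p = 0.000158, 0.298 with an estimated correlation, same-set 0.22) rose with Cyp12c1 (1.95 ± 0.18) and Cyp4e1 (1.11 ± 0.11). mthl8 reached 17.0 ± 2.58 CPM, a ratio of 1531 [274, 60533].

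Signalling genes of neurons fell in JmjC. Neuropeptides had a median of -0.82 (camera adjusted p = 5.04e-13, 0.0692 with an estimated correlation), -0.74 same-set. Here 0 rose and 18 fell (1 and 19 in the list alone). AstC fell from 66.2 ± 4.71 to 23 ± 0.745 CPM and Tk by 1.30. Synaptic genes had a median of -0.36 (camera adjusted p = 3.95e-14, 0.296 with an estimated correlation), -0.31 same-set. Of these, 0 rose and 24 fell (0 and 29 in the list alone). Gad1 measured 327 ± 18.2 CPM against 576 ± 46.4 CPM in WT, with VGlut at -0.84 ± 0.092. Photoreceptor genes (-0.18, camera adjusted p = 0.000943, 0.331 with an estimated correlation, same-set -0.12) fell with eys, which opens the space between rhabdomeres (-0.72 ± 0.12), and the channel trp (-0.42 ± 0.087). Clock genes (-0.20, camera adjusted p = 0.0311, 0.227 with an estimated correlation) fell with per (-1.08 ± 0.23) and Pdp1 (-0.45 ± 0.13, same-set adjusted p = 0.109 by edgeR, and 0.113 without JmjC 2), and did not pass without WT 3 or WT 4 (camera adjusted p = 0.0533 and 0.0607). Muscle genes (-0.34, camera adjusted p = 0.000153, 0.331 with an estimated correlation, same-set -0.23) fell with TpnC41C (-1.57 ± 0.28), and Act79B, an adult muscle actin, had -3.32 ± 0.77 (same-set -1.38, -2.71 without WT 1). Scp1, a sarcoplasmic calcium-binding protein, had -2.72 ± 0.79 (edgeR adjusted p = 0.0144, same-set -0.35, adjusted p = 0.581) and did not pass without JmjC 1, 2 or 3 (0.0571, 0.0630 and 0.0557). CG9377 (-3.48 ± 0.72, same-set -1.46) and CG31205 (-3.12 ± 0.53, same-set -1.86) fell as well.

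Energy and translation genes also fell in JmjC. Oxidative phosphorylation had a median of -0.47 (camera adjusted p = 3.95e-14, 0.331 with an estimated correlation), -0.28 same-set. Among these genes, 1 rose and 60 fell (1 and 68 in the list alone). The complex I subunit ND-49 measured 204 ± 2.69 CPM against 279 ± 13.4 CPM, with ATPsynC (-0.48) and ATPsynE (-0.63). Mitochondrial genome encoded subunits (-0.94, camera adjusted p = 0.00178, 0.331 with an estimated correlation, same-set -0.52) fell with mt:ND4 (-1.19 ± 0.25) and mt:ND5 (-1.29 ± 0.28). The TCA cycle (-0.35, camera adjusted p = 1.71e-06, 0.227 with an estimated correlation) fell with muc of pyruvate dehydrogenase (-0.57 ± 0.07) and aconitase mAcon1 (-0.47 ± 0.074), and glycolysis (-0.27, camera adjusted p = 0.00025, 0.299 with an estimated correlation) with Ald1 (-0.40) and Pfk (-0.36). Mitochondrial ribosomal proteins (-0.26, camera adjusted p = 5.59e-06, 0.375 with an estimated correlation) were -0.12 same-set (camera adjusted p = 0.0725), with mRpS9 (-0.35), mRpL21 (-0.59) and mRpS35 (-0.44). Ribosome biogenesis (-0.27, camera adjusted p = 0.000347, 0.372 with an estimated correlation, same-set -0.39) fell with Fib (-1.11 ± 0.15) and the snoRNP protein hoip (-1.08 ± 0.19), and translation factors (-0.15, camera adjusted p = 0.00896, 0.396 with an estimated correlation, -0.09 without WT 3, camera adjusted p = 0.0533) with eIF4A (-0.42) and the repressor eIF4EHP (-0.69). With WT 1 and 2 only both medians were above 0, at 0.051 and 0.11.

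In the equal-weight mean of the 5 variants, ribosome assembly and clock genes were lower and muscle, TCA cycle and glycolysis genes higher. 1320 genes rose and 1583 fell (1568 and 1512 same-set). Ribosomal protein genes had a median of -0.30 (camera adjusted p = 4.06e-27, 0.165 with an estimated correlation), -0.30 same-set. Of these, 0 rose and 63 fell (0 and 71 in the list alone). Strain means held RpL27 at 498 ± 54.3 CPM (n = 5 strain means) against 750.0 ± 65.4 CPM, RpL28 at -0.44 ± 0.055 and the stalk protein RpLP0 at -0.53 ± 0.067. Ribosome biogenesis had a median of -0.50 (camera adjusted p = 1.82e-14, 0.165 with an estimated correlation), -0.38 same-set, led by Nopp140 (-0.56 ± 0.076) and Nnp-1 (-0.61 ± 0.086). Translation factors had a median of -0.23 and a mean of 0.019 (camera adjusted p = 2.54e-08, 0.165 with an estimated correlation), with eIF3a (-0.26 ± 0.039) and eEF1beta (-0.41 ± 0.061). Muscle genes (0.45, camera adjusted p = 2.69e-11, 0.165 with an estimated correlation, same-set 0.44) rose with TpnC25D (0.78 ± 0.074) and Mf (0.50 ± 0.064). Oxidative phosphorylation (0.19, camera adjusted p = 9.21e-08, 0.713 with an estimated correlation, 0.12 without WT 5) rose with ND-ACP (0.51 ± 0.08), blw (0.34 ± 0.06) and ATPsynC (0.32 ± 0.057). It was 0.019 with the replicate number as a block (camera adjusted p = 0.459), and lower, at -0.080, with WT 1 and 2 only (camera adjusted p = 0.0423). The TCA cycle (0.14, camera adjusted p = 0.000369, 0.396 with an estimated correlation) rose with Idh3a (0.34) and Mdh2 (0.30; edgeR adjusted p = 0.0569 without WT 4 and 0.0513 without WT 5), and glycolysis (0.14, camera adjusted p = 0.00112, 0.396 with an estimated correlation) with Pfk (0.21) and Gapdh1 (0.36). Proteasome genes (0.14, camera adjusted p = 0.000561, 0.77 with an estimated correlation, 0.09 without WT 5) rose with Rpt4 (0.32) and Prosalpha5 (0.33; edgeR adjusted p = 0.0801 without WT 4 and 0.0844 without WT 5). D234G (0.78) carried this (-0.12 to 0.11 in the others), and it was 0.015 in the block fit (camera adjusted p = 0.733) and -0.037 with WT 1 and 2 only (0.439).

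Clock repressors fell in the mean of 5, where per measured 29.7 ± 5.92 CPM against 58.6 ± 19.5 CPM and vri had a log2 fold of -1.24 ± 0.14, within a clock list at -0.16 (camera adjusted p = 0.00274, 0.087 with an estimated correlation). Histone methylation enzymes (-0.078, camera adjusted p = 0.0486, 0.728 with an estimated correlation) were -0.071 same-set (camera adjusted p = 0.0674), with Kdm2 (-0.26 ± 0.045) and E(z) (-0.22 ± 0.053) lower. The list did not pass without WT 2, 4 or 5 (camera adjusted p = 0.0761, 0.0787 and 0.169). Kdm5 itself rose by 0.16 ± 0.042 (edgeR adjusted p = 0.00754). Mitochondrial ribosomal proteins had a median of -0.064 (camera adjusted p = 0.133) and -0.12 same-set (camera adjusted p = 0.000608). The other lists, from alternative ribosomal protein paralogs (-0.44) to glutathione enzymes (0.089), were not called (camera adjusted p of 0.0802 or more).

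**Figure D3:**
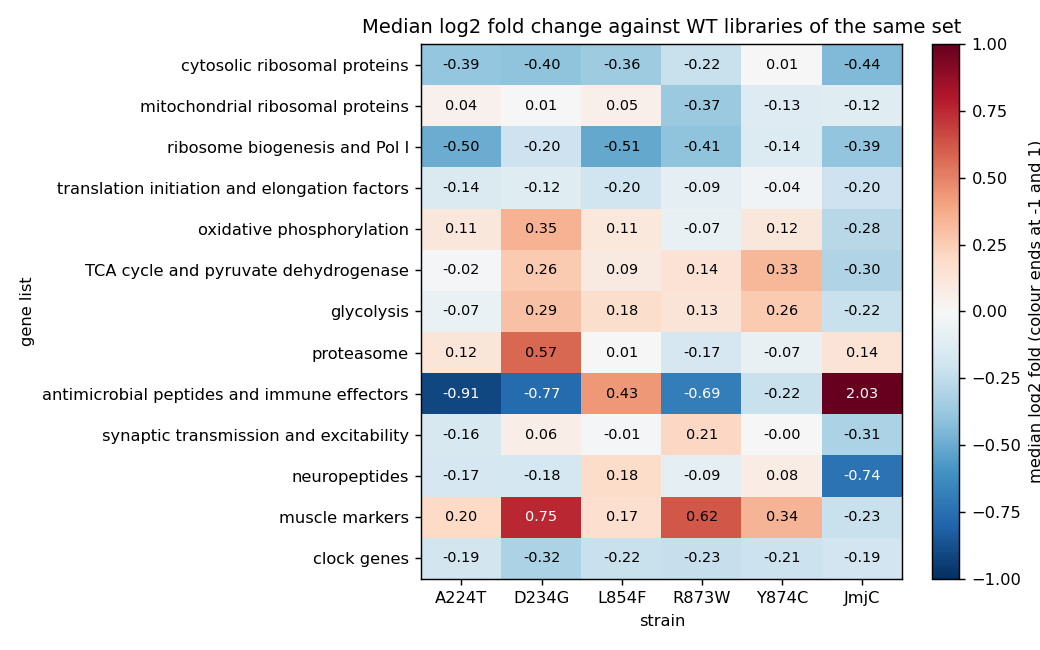
Median log2 fold (colour) of selected gene lists (y) in each strain (x), against the same-set WT libraries. Cytosolic ribosomal proteins were at 0.0065 in Y874C, and oxidative phosphorylation was at -0.075 in R873W.

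In the mean of 5, lncRNA:CR44946 reached 12.4 ± 5.28 CPM over all libraries of the 5 variants against 2.57 ± 0.604 CPM (log2 fold 2.15 ± 0.12). It was followed by CG3777 (2.15 ± 0.28), CG5653 (2.06 ± 0.19), IntS12 (1.87 ± 0.17) and CG10560 (1.82 ± 0.16). The cuticle gene Cpr76Bd (1.80 ± 0.29), CG34375 (1.74 ± 0.19), Obp8a (1.58 ± 0.14) and CG11029 (1.42 ± 0.33) came next. mthl8 summed over the 5 variants had a ratio of 4025 [722, 158987] to WT, though D234G held 0 counts. Adh fell by 2.43 (edgeR adjusted p = 2.73e-06), Srg3 by 2.30 and CG4757 by 2.02, and frac, an extracellular matrix protein, had -3.78 ± 0.63 (same-set -2.80, -3.03 without WT 2, but 0.56 with WT 3 to 5 only, edgeR adjusted p = 0.176). The other 6 largest decreases were smaller without WT 3 but passed (edgeR adjusted p = 0.00178 to 0.00762): CG45080 (-8.24 ± 1.26, -6.38 without WT 3), whe (-7.30 ± 1.23, -5.82), CG16826 (-6.85 ± 1.16, -5.33), lcs (-6.78 ± 1.11, -5.33), CG33109 (-6.11 ± 0.92, -4.42) and Ag5r (-5.06 ± 0.86, -3.42). 47 genes were lower and 49 higher in each of the 5 variants (28 and 48 same-set), of which 29 and 36 moved alike in JmjC too. The comparisons share WT libraries, which the 0.129 and 0.195 genes due for independent lists of these sizes leave out. In 20 simulations of unchanged groups the overlap was 0, fixed beforehand by a mean of 0.04 calls per simulated strain (4.79 with the sets). Neither value shows what the shared WT libraries add. 1 ribosomal protein gene was lower in all 5, and 17 in the 4 variants other than Y874C. 92 genes were lower in each of 5 without WT 1, and 31 without Y874C 2. Without L854F 1, 2 or 3 there were 20, 20 or 25 lower and 25, 23 or 28 higher. In an F-test without WT libraries 8502 genes (70.3%) differed among the 5 variants of both sets, and 6682 among the 3 of set 1. Both include libraries with male reproductive transcripts. A224T and L854F, of set 2, differed at 788.

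Over 8219 genes, log2 folds of strains of the same set correlated at r of 0.42 to 0.73 (6 pairs). Those of different sets did at -0.05 to 0.29 (9 pairs). Simulated unchanged groups sharing the WT libraries gave 0.34 to 0.40. With each set's own WT levels they gave 0.74 to 0.86 within a set, above the observed r, and -0.56 to -0.54 between sets, below it. Covariances spanned -0.0169 to 0.386, against 0.0139 to 0.0151 simulated and -0.0666 to 0.133 with the sets. The highest, D234G with R873W, kept libraries with male reproductive transcripts. With different WT libraries for the 2 strains of a pair, r spanned -0.09 to 0.63.

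Compared with the mean of the 5 variants, JmjC had higher immune and detoxification genes and lower neuropeptide, muscle and respiratory genes. 2542 genes were higher and 2378 lower. With library size as the only scaling these counts were 3728 and 1551, and the median of all genes was 0.12 higher. Same-set values here set JmjC against the mean of A224T and L854F, where 1387 genes were higher and 1655 lower. Immune effectors had a median of 2.48 (camera adjusted p = 7.57e-09, 0.3 with an estimated correlation), 2.34 same-set. edin (9.51 ± 0.78, 7.77 without JmjC 2), drosomycin Drs (2.84 ± 0.53), the serpin Spn88Eb (2.73 ± 0.23), the bomanin BomS5 (2.70 ± 0.30, same-set 0.82) and Tep2 (1.04 ± 0.095) were higher. Hemocyte (0.52, camera adjusted p = 0.002, 0.442 with an estimated correlation) and fat body (0.78, camera adjusted p = 0.00221, 0.3 with an estimated correlation) genes were higher, with Sr-CI (0.98 ± 0.15), Hml (0.83 ± 0.13; same-set 0.37, edgeR adjusted p = 0.0899), Fatp1 (0.67 ± 0.09) and Amy-p (1.92 ± 0.27). P450 genes (0.32, camera adjusted p = 4.91e-06, 0.178 with an estimated correlation) were higher with Cyp12c1 (2.38 ± 0.14) and Cyp6t3 (1.63 ± 0.11). Kdm5 had a log2 fold of -0.25 ± 0.051 (edgeR adjusted p = 0.000669), and -0.13 with library size only (edgeR adjusted p = 0.0660).

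Neuropeptides were lower in JmjC than in the mean of 5, with a median of -0.95 (camera adjusted p = 1.35e-11, 0.104 with an estimated correlation) and -0.73 same-set, led by AstC (-1.37 ± 0.068) and Proc (-1.01 ± 0.086). Synaptic genes (-0.41, camera adjusted p = 3.16e-15, 0.207 with an estimated correlation, same-set -0.23) were lower with Gad1 (-0.86 ± 0.065) and VGlut (-0.77 ± 0.083). Photoreceptor genes (-0.14, camera adjusted p = 0.025, 0.617 with an estimated correlation) were 0.048 same-set (camera adjusted p = 0.803), with eys (-0.71 ± 0.10) and Galphaq (-0.36 ± 0.05) lower. This list did not pass without A224T 1, D234G 2, R873W 3, Y874C 2, JmjC 1 or JmjC 2 (camera adjusted p = 0.0636, 0.102, 0.0567, 0.0622, 0.053 and 0.1). Muscle genes (-0.84, camera adjusted p = 1.91e-11, 0.178 with an estimated correlation, same-set -0.42) were lower with Mf (-0.85 ± 0.081), TpnC25D (-0.97 ± 0.094) and Act79B (-3.79 ± 0.75). Oxidative phosphorylation (-0.66, camera adjusted p = 7.16e-20, 0.229 with an estimated correlation, same-set -0.34) was lower with ATPsynC (-0.81 ± 0.073), ND-49 (-0.55 ± 0.053) and blw (-0.73 ± 0.076). Mitochondrial genome encoded subunits (-0.99, camera adjusted p = 0.00534, 0.442 with an estimated correlation) were lower with mt:ND4 (-1.45 ± 0.23) and mt:ND5 (-1.58 ± 0.26, same-set adjusted p = 0.127 by edgeR). The TCA cycle (-0.52, camera adjusted p = 7.54e-09, 0.178 with an estimated correlation) was lower with Idh3a (-0.77 ± 0.075) and muc (-0.63 ± 0.063), glycolysis (-0.38, camera adjusted p = 1.02e-06, 0.178 with an estimated correlation) with Pfk (-0.57 ± 0.052) and Pglym78 (-0.60 ± 0.073). Mitochondrial ribosomal proteins (-0.21, camera adjusted p = 0.00142, 0.713 with an estimated correlation) were lower with mRpS33 (-1.23 ± 0.20), mRpS9 (-0.30) and mRpL52 (-0.55). Cytosolic ribosomal proteins (-0.14, camera adjusted p = 0.00104, 0.713 with an estimated correlation, -0.08 without JmjC 3) were -0.065 same-set (camera adjusted p = 0.195), with RpS2 (-0.51 ± 0.088), RpLP2 (-0.50 ± 0.095) and RpS14a (-0.72 ± 0.14). The cuticle gene Acp1 (-4.41 ± 1.11), CG7214 (-5.22 ± 1.26) and CG4836 (-3.87 ± 1.14; edgeR adjusted p = 0.0517 without JmjC 2; same-set -1.67, adjusted p = 0.465) were the other largest decreases.

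Ribosome profiling followed messages bound by ribosomes after knockdown of kdm5 in neurons. In the authors' deposited table, read here as log2 folds of knockdown against control, Kdm5 fell by 0.97 in RNA (adjusted p = 2.06e-22 in the table) and by 2.02 in footprints (2.2e-45). Over 13963 genes of the authors' deposited table, 1206 rose and 1279 fell in RNA, and 842 rose and 2095 fell in footprints. With a mean count of 100 or more in both columns of the authors' deposited table, 843 rose and 824 fell in RNA, and 741 and 875 in footprints. Cytosolic ribosomal protein genes in the authors' deposited table fell in RNA, with a median of -0.48, and 0 rose and 78 fell of 82. The central range over 10000 random lists of like abundance was -0.06 to 0.12. Their footprints in the authors' deposited table had a median of -0.29 (random lists -0.16 to 0.039), and 1 rose and 34 fell, with a footprint minus RNA median of 0.17. RpS14b (-0.74 RNA, -0.75 footprints), RpL26 (-0.63, -0.84) and RpS12 (-0.58, -0.93) fell in both columns of the authors' deposited table, and RpS2 (-0.71, -0.27) and RpS20 (-0.73, -0.62) fell in RNA. RpL3, at -0.57 and -0.78 in the authors' deposited table, is also the tagged transgene of this experiment. Respiratory genes fell in footprints and not in RNA. In the authors' deposited table oxidative phosphorylation had an RNA median of 0.069 (random lists -0.05 to 0.075) and a footprint median of -0.33 (random lists -0.13 to 0.027), and in footprints 0 rose and 53 fell of 92. COX7AL2 (-1.56), COX7A (-0.84), ND-39 (-0.60) and blw (-0.56) fell in footprints of the authors' deposited table, whereas RNA of Cyt-c-p (0.63) and COX7AL (1.61) rose. Mitochondrial ribosomal proteins in the authors' deposited table had medians of -0.10 in RNA and 0.049 in footprints, both within the random lists, with mRpL23 (1.22), mRpS29 (0.79) and mRpL11 (0.66) higher in footprints and mRpL10 (-0.42), mRpL21 (-0.52) and mRpS30 (-0.35) lower in RNA.

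**Figure D4:**
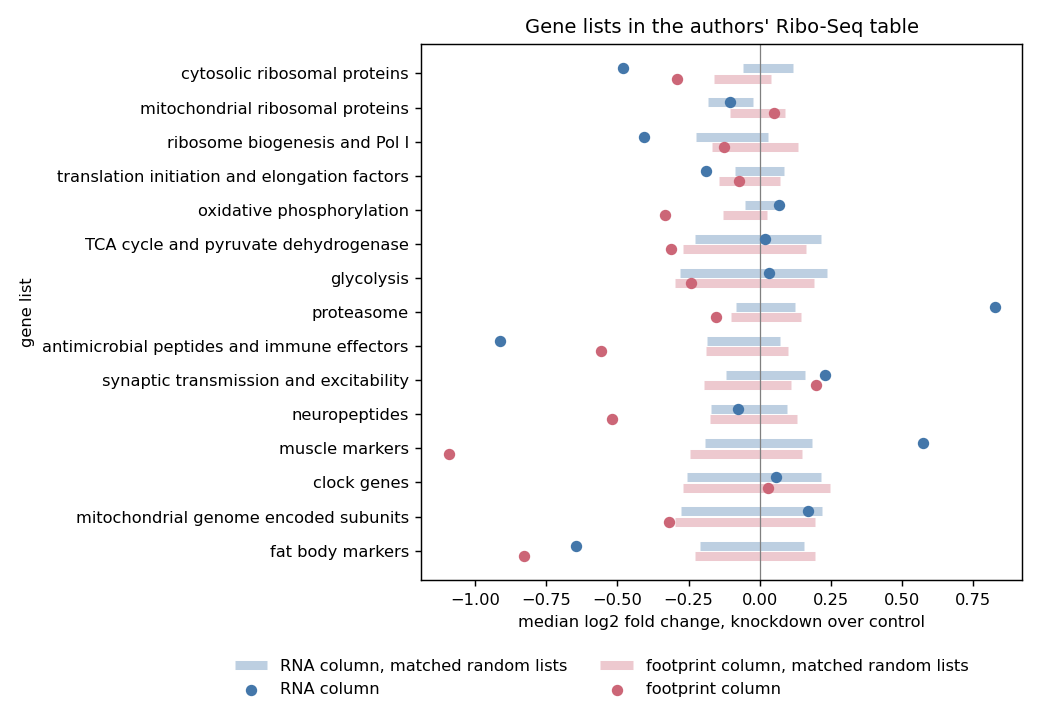
Median log2 fold of knockdown against control (x) for selected gene lists (y) in RNA and in ribosome footprints of the authors' deposited table, with bars for the central range of matched random lists. Proteasome genes were at 0.83 in RNA and -0.15 in footprints.

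The widest gaps between the RNA and footprint columns lay in degradation and contractile genes. Since the cell content of the 2 columns is not known, these gaps are not read as changes of translation in neurons. In the authors' deposited table proteasome genes had an RNA median of 0.83 and 32 rose and 0 fell of 32, while their footprint median was -0.15 and 0 rose and 7 fell. Muscle genes, which neurons express little, had medians of 0.57 in RNA and -1.09 in footprints of the authors' deposited table, and in footprints 0 rose and 20 fell. The TCA cycle (0.018 and -0.31), glycolysis (0.032 and -0.24) and mitochondrial genome encoded subunits (0.17 and -0.32) had lower footprint than RNA medians in the authors' deposited table. Neuropeptides were at -0.077 in RNA and -0.52 in footprints of the authors' deposited table, and 1 rose and 14 fell in footprints, while synaptic genes were at 0.23 and 0.20 and photoreceptor genes at 0.22 and 0.36. Immune effectors (-0.91 and -0.56) and fat body genes (-0.65 and -0.83) were lower in both columns of the authors' deposited table, with DptA (-2.60 and -2.18), DptB (-2.34 and -2.28) and AttC (-1.82 and -1.02). Ribosome biogenesis (-0.41 and -0.13), translation factors (-0.19 and -0.073) and hemocyte markers (-0.49 and -0.22) had lower medians in RNA than in footprints of the authors' deposited table.

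Single genes of the authors' deposited table with the largest RNA rises were the pigment gene y (4.47, footprints 2.17), CG5653 (2.56 and 1.86), l(3)mbn (2.51 and 0.68) and CG14770 (2.40 and 0.47). The largest footprint rises of the authors' deposited table included CG13022 (2.39), CG14692 (2.17) and CG9150 (1.88), and CG42807 fell in both (-1.96 and -2.13). CG16826 (-7.01), whe (-6.22), CG10097 (-5.58) and CG18180 (-5.18) had the largest footprint decreases of the authors' deposited table, with RNA folds of -0.61, -0.57, -0.81 and -0.37. The translation efficiency column of the authors' deposited table was not the difference of the other 2 columns, so no finding rests on it. The authors' deposited table labels 9980 as no change, 1787 as buffering, 1561 as translation and 635 as mRNA abundance.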

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

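The random splits were planned before the data were examined, and all other tests in this part were chosen after the results were seen.

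Ribosomal protein transcripts were lower in 5 strains but not in Y874C, and 4 sources were weighed. The 2 library sets would not give the decrease of A224T, D234G, L854F and JmjC, which held same-set. R873W (same-set -0.22) stays open, as random splits matched its median. Nor would the sets give the gap: Y874C stood 0.34 above D234G and R873W of its set. Scaling was not the source: with library size only the highest of the 5 medians was -0.28. Other genetic differences could not be told apart from the KDM5 change. mthl8, with 1 count in WT, reached 5 CPM in 4 strains, which may mark another background.

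Male reproductive transcripts stood out in some D234G and R873W libraries, from a marker list written after the largest rises were seen. Of 25 detected markers, 12 of accessory gland and 13 of testis, 100% were highest in a D234G or R873W library, but most stayed under 1 CPM elsewhere, so the filter nearly fixed this share and it decides nothing. Summed levels were 711, 29.8 and 673 CPM in D234G 1, 2 and 3 and 55.6, 167 and 229 CPM in R873W 1, 2 and 3, against at most 39.1 CPM elsewhere. D234G 2 held 4.43% of the lower of the other 2 sums, so a change in all D234G flies could not account for it. Male body tissue in single head samples stays open.

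The te column of the authors' deposited table would equal footprint minus RNA folds if it were a ratio. Over 5058 transcripts of that table with a footprint mean of 1000 or more, it lay within 0.1 of that difference for 26.4% and of the footprint fold alone for 99.0%, with median absolute gaps of 0.210 and 0.0201. It was therefore not the ratio, and nearly equalled the footprint fold except in 51 transcripts. With these its slope on the footprint fold was 1.33 ± 0.0172 and r 0.747, and how they arose stays open.

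Random splits of the libraries of WT and 1 strain (56 each, the real one included) asked how often a grouping calls as many genes. As many calls came from 1 split for A224T (1786, highest other 1546 with WT 1, 2 and 5 together), 1 for R873W (5284, other 3896 with WT 3, 4 and 5) and 1 for JmjC (3243, other 2261 with WT 1, 2 and 5). For D234G there were 2 (5350, other 5599) and for Y874C 2 (2334, other 3830). The other split was WT 3 to 5 in both, which follows the sets. Within set 1 D234G had 3752 calls and Y874C 1545. L854F had 5 splits with as many calls (942, highest other 1207 with WT 1, 2 and 5), so these splits do not exclude chance. Within set 2 L854F had 1371 calls. The ribosomal protein median was reached by 1 split in A224T (-0.41, highest other 0.35), 1 in D234G (-0.42, other 0.34), 1 in L854F (-0.37, other -0.33 with WT 5, L854F 2 and 3) and 1 in JmjC (-0.42, other 0.37), the positive ones with WT 2, 3 and 4 together. It was reached by 4 in R873W (-0.24, other 0.25 with WT 1, 2 and 3) and 31 in Y874C (-0.05, other 0.15 with WT 2, 3 and Y874C 3), within what random groups gave. Of 100 splits, 1 reached the calls in the mean of 5 (2903, other 1948) and its ribosomal protein median (-0.30, other 0.30). 1 reached the F-test (8502, other 2756) and JmjC against the mean of 5 (4920, other 2376). The same held for genes lower (47, other 0) and higher (49, other 0) in each of 5. Mixing of strains nearly fixed these 0s, which decide nothing.

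Single WT libraries stood apart for 15 of the 187 named genes tested, where 9.35 were due by chance at about 1 in 20. For 4 of these, with a ratio of 1, counts in 1 library and 0 in the others fixed the outcome, leaving 11. By gap over range, WT 3 was highest for mthl8 (1; 0.0598 CPM, next 0), CG8851 (1; 0.0598, next 0), CG13947 (0.723; 37.9, next 10.5), RpS13 (0.742; 776, next 691), CG16826 (0.770; 1629, next 375), CG45080 (0.853; 302, next 44.3), lcs (0.723; 425, next 118), CG33109 (0.813; 84.1, next 15.8) and Ag5r (0.790; 151, next 31.9). WT 5 was lowest for per (0.770, 24.7 CPM, next 61.2) and mRpS18A (0.715, 7.18, next 8.50). WT 2 was highest for CG17097 (1, 0.104 CPM, next 0) and IntS12 (0.785, 3.13, next 2.17), and WT 4 for CG31872 (1, 0.109 CPM, next 0) and Drs (0.865, 119 CPM, next 22.5). Between groups of the same fit, ribosomal proteins differed by 0.35 between Y874C and the 4 other variants. JmjC differed from the mean of 5 by -0.66 for oxidative phosphorylation, 2.48 for immune effectors and -0.95 for neuropeptides.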

How the results depend on the processing

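Alternatives using subsets of WT libraries, libraries without male transcripts, transposable element insertions or a Ribo-Seq mean count of 100 were chosen after the results were seen, and the others before.

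Of 433 alternatives to 18 counts and list values, 369 left the result the same, 6 weakened it, 1 strengthened it, 4 reversed it and 53 moved it by more than 1.5 times. Of 6451 alternatives for 300 named gene results, 6216 left it the same, and of 2032 for 88 called lists, 1785. DESeq2, RLE and both filters moved no count over 1.5 times. The Ribo-Seq count alternatives were not run. The limits are small groups, 2 library sets that divide the strains, 2 shallow D234G libraries and shared WT libraries. The cause was not tested for the values below.

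With the replicate number as a block, Y874C had 1347 calls and the mean of 5 1521, and the ribosomal protein median of Y874C was -0.066 (camera adjusted p = 0.0286). In the block fit these called lists did not pass: fat body (adjusted p = 0.0599) and histone methylation enzymes (0.0738) in D234G, oxidative phosphorylation in R873W (0.587), neuropeptides in Y874C (0.338), translation factors in JmjC (0.0677), and oxidative phosphorylation (0.459), proteasome (0.733) and histone methylation enzymes (0.459) in the mean of 5.

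A fold of 1.5 or more left 754 calls in A224T, 3143 in D234G, 394 in L854F, 2714 in R873W, 1055 in Y874C, 1300 in JmjC, 1062 in the mean of 5 and 1888 in JmjC against that mean. With only WT and the strain in the fit there were 717, 2350, 315, 3079 and 724 in A224T, D234G, L854F, R873W and Y874C. With an estimated correlation the ribosomal protein lists lost their calls: A224T (-0.41, adjusted p = 0.244), D234G (-0.42, 0.272), L854F (-0.37, 0.169), R873W (-0.24, 0.599), JmjC (-0.42, 0.227) and the mean of 5 (-0.30, 0.165). With library size only Kdm5 in JmjC was 0.051.

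With WT 1 and 2 only, calls were 3684 in A224T, 3197 in L854F and 1545 in Y874C, and 109 genes were lower and 130 higher in each of 5. Medians changed sign for ribosomal proteins in Y874C (0.0065), translation factors in A224T (0.028) and JmjC (0.11), ribosome biogenesis in A224T (0.031) and JmjC (0.051), oxidative phosphorylation in R873W (-0.075) and the mean of 5 (-0.080), and proteasome in the mean of 5 (-0.037). With WT 3 to 5 only, Y874C had 4108 calls, 249 genes were lower and 144 higher in each of 5, frac in the mean of 5 was 0.56, and medians changed sign for mitochondrial ribosomal proteins in A224T (0.045) and L854F (0.050), oxidative phosphorylation in A224T (0.11) and L854F (0.11) and proteasome in L854F (0.0054). Against same-set libraries these 5 values, and those above of Y874C and R873W with WT 1 and 2 only, were the same. There 28 genes were lower in each of 5. JmjC against the mean of A224T and L854F, of its own set, had 3042 calls and a photoreceptor median of 0.048.

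Without D234G 1 and 3, which leaves n = 1, D234G had 1162 calls, and 25 genes were lower and 28 higher in each of 5. Without R873W 2 and 3, again n = 1, R873W had 2026 calls, with 25 and 29. Without all 4, D234G had 1057 calls and R873W 2397, with 14 lower and 21 higher, and 5326 genes differed among the variants. In the authors' deposited table all transcripts gave 6595, 6843 and 8219 calls in the rna, rfp and te columns, and genes with a mean count of 100 or more 1616 in rfp and 1842 in te.

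Leaving out 1 library gave these lowest and highest values: A224T 930 to 2061 calls, D234G 4242 to 5935, L854F 395 to 1106, R873W 4167 to 5422, Y874C 1238 to 2915, JmjC 2084 to 3429, the mean of 5 2102 to 3521, JmjC against that mean 3440 to 5359, F-test 7953 to 9326, lower in each of 5 20 to 92 and higher 23 to 53. The ribosomal protein median spanned -0.46 to -0.36 in A224T, -0.48 to -0.35 in D234G, -0.44 to -0.30 in L854F, -0.28 to -0.18 in R873W, -0.069 to 0.017 in Y874C, -0.48 to -0.39 in JmjC and -0.33 to -0.24 in the mean of 5. It was above 0 in Y874C without WT 3 or Y874C 1. Of 952 such alternatives for called lists 49 lost the call and 0 reversed, among them oxidative phosphorylation and mitochondrial ribosomal proteins in A224T and L854F.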

Other observations

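These levels were looked at after the results were seen, and no test in this part was planned.

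Acp36DE, a seminal fluid protein that supports sperm storage, measured 219, 0 and 82 CPM in D234G 1, 2 and 3, and 2.58, 35.6 and 179 CPM in R873W 1, 2 and 3. Its order over these libraries was not that of the summed testis markers, which were highest in D234G 3 (560.3 CPM) and R873W 2 (102 CPM).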
